A study of Mus musculus with 8 samples.

How the data were processed

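RNA from the spleens of B6D2F1J mice, the F1 hybrid of the C57BL/6 and DBA/2 strains, was measured on 8 Illumina MouseRef-8 v2.0 BeadChip arrays, 1 array per sample. Each probe on such an array is a set of beads that carry the same oligonucleotide, and biotin-labelled RNA that binds to it is read as brightness. The labels name the tissue, the donor strain, day 14 after engraftment and a recipient age of 10 weeks. Samples were grouped by the donor named in their titles, as 4 with a DBA donor and 4 with a B10.D2 donor. No array of a recipient without donor cells was used here. The labels do not say that replicates were separate mice, so p-values measure the spread between these samples, which may in part be technical.

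Per the file headers, the deposited table of non-normalized values holds, for each probe and array, the mean bead intensity on a linear scale. Per the file headers, the same deposited table gives a detection p-value for each probe and array, which sets a probe against the negative controls of its own array. A second deposited table holds intensity values that the authors had processed further; its steps are not given in the sources used here. Its values showed that it was on a linear scale, reached down to -16.5 and had array medians of 13.9 to 14, and within each array its rank order equalled that of the non-normalized intensity (rank correlation of 1). This second table served as an alternative. The submitters' processing notes name GenomeStudio with no version. The genome build behind the probes is not given in the sources used here, so no coordinates are reported.

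Intensities were background-corrected by normexp with the background estimated from the detection p-values and an offset of 16, quantile-normalized between arrays and put on a log2 scale (the neqc method of limma 3.58.1 in R 4.3.3). The offset shrinks differences of dim probes. Of 25697 probes, 23978 had 1 gene symbol in the platform annotation, 0 had several and 1719 were not listed there and are unnamed here. Of the named probes, 23962 were matched by Entrez number to the GRCm38.p6 gene table, which changed 0 symbols. Probes with a detection p under 0.05 on at least 4 of the 8 arrays were tested, without regard to group, which left 12950 probes of 9028 genes, with 751 unnamed probes among them. Differences were fitted with limma (lmFit and eBayes, two-sided moderated statistic, DBA donor minus B10.D2 donor) and adjusted by Benjamini-Hochberg over all tested probes. A probe passed at an adjusted p under 0.05. A gene with several tested probes is represented by the probe with the highest mean, and other probes are given where they bear on the gene. Values are means of normalized log2 intensity with the SD over 4 arrays. Bounds written as "at least" set the mean of the brighter group against, per array, the higher of the dim probe's own value and the lowest value among detected probes. The number of arrays limits the precision.

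The test, the filter, 26 gene lists and the rule for named genes were fixed before the data were examined. The 25 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes and adjusted over the 25. Camera with an estimated correlation, camera on ranks, fry, counts of members adjusted over the list alone and the exact two-sided permutation test of each list's mean per array (70 arrangements, smallest possible p of 0.0286) stood beside it. The rule named up to 10 genes per direction that passed and whose groups did not overlap, with symbols of the Riken, LOC and Gm types left out. It also named up to 3 members of each list that passed, or 2 with the smallest p where none did. Finally it named Ifng, Gzmb, Prf1, Fasl, Il21, Il10, Il2, Tnf, Bcl6, Cd4, Cd8a, Ms4a1, Sdc1 and Ncr1 in any case. Genes named outside this rule are said to be so.

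The fit was tested on simulated data for this comparison, with 12950 probes of which 50 were changed at each size. It recovered 50% of probes changed 1.5-fold, 92% of those changed 2-fold and 100% of those changed 3-fold and 4-fold. It called 8 unchanged probes, and 0 probes when none had been changed. In a further simulated draw, 5 of 5 shifted lists and 0 of 15 unshifted lists of random genes were called. Probes were simulated independently of each other, so this does not measure false calls of probes or of lists where genes move together. The plasma cell list, for example, had an estimated correlation of 0.831. Alternatives covered the background correction, offset, normalization, source of values, dim-probe filter, probe summary, variance model, array weights, ordinary per-probe statistic, replicate block, set test, thresholds and the loss of each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.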

Results

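Spleen RNA was profiled 14 days after engraftment in the parent-into-F1 model of lupus, in which lymphoid cells from a parental strain are transferred into F1 hybrid mice and respond to the recipient. The recipients were 10-week-old B6D2F1J mice that had received cells from a DBA donor (4 arrays) or from a B10.D2 donor (4 arrays). The label B10.D2 names neither parental strain of these recipients, so the word parental is not literal for that donor. The comparison asks how the spleen's RNA at this time differs with the donor strain. Between 12601 and 13320 probes were detected per array. Median raw intensity was lower on the DBA donor arrays (118.9 ± 5.39, SD, n = 4, range 113.2 to 124.8) than on the B10.D2 donor arrays (133.3 ± 6.84, SD, n = 4, range 126.4 to 142.1), with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 arrays can give. Normalized profiles correlated at 0.98 to 0.994 within groups and at 0.978 to 0.992 between groups, across probes, which are not independent replicates.

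The chemokines Ccl8 and Ccl12, both attractants of monocytes and other leukocytes, rose most in DBA donor spleens. Ccl8 stood at 8.14 ± 0.20 in DBA donor spleens and 6.09 ± 0.58 in B10.D2 donor spleens (SD, n = 4; log2 difference 2.05, SE 0.24, 95% confidence interval 1.51 to 2.59, 4.15-fold, limma adjusted p = 0.0183). Ccl12 was 3.48-fold higher (log2 difference 1.80, SE 0.24, limma adjusted p = 0.0321), and its other tested probe differed by 1.58 (limma adjusted p = 0.00802). Mcpt4, a chymase of mast cell granules, was 2.42-fold higher (log2 difference 1.27, SE 0.17, limma adjusted p = 0.0321). Tsc22d3, the glucocorticoid-induced leucine zipper protein, was the only named gene to pass in the other direction, with a log2 difference of -0.71 (SE 0.10, limma adjusted p = 0.0463) and -0.42 on its other probe (unadjusted p = 0.010). With probes averaged per gene it was -0.56 (limma adjusted p = 0.105), and that call was lost, as it was with the replicate block.

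A further 3 named genes passed, all higher in DBA donor spleens. Zan, which encodes the sperm protein zonadhesin, was 2.33-fold higher (limma adjusted p = 0.0302) and was detected on 4 of 4 DBA donor arrays and 2 of 4 B10.D2 donor arrays. Atg4d, a cysteine protease of autophagy, was 2.15-fold higher (6.94 ± 0.09 against 5.84 ± 0.27, SD, n = 4, limma adjusted p = 0.0183). Rrp1b, a nucleolar protein, was 1.70-fold higher (limma adjusted p = 0.0463), while its other tested probe differed by 0.40 (unadjusted p = 0.0570). Its call was lost with probes averaged per gene (0.58, limma adjusted p = 0.160) and with the replicate block. The unnamed probe ILMN_1251123 was 2.93-fold higher (limma adjusted p = 0.00802). In total 9 of 12950 probes passed, 8 higher and 1 lower in DBA donor spleens, and 7 of them, all higher, differed at least 2-fold. The groups of arrays did not overlap for any of the 9. Sizes depended on the processing: over the alternatives the log2 difference of Ccl8 ran from 1.19 to 2.29, of Ccl12 from 0.97 to 1.98, of Mcpt4 from 0.53 to 1.42, of Zan from 0.42 to 1.35 and of Atg4d from 0.51 to 1.19. At an unadjusted p under 0.05 there were 1878 probes, 921 higher and 957 lower, where chance alone gives 648. The groups did not overlap for 8.37% of tested probes, against 2.86% by chance. The count of 9 depended on single arrays: it was 0 without B10.D2 donor replicate 2, DBA donor replicate 3 or DBA donor replicate 4 (1275, 1233 and 1996 probes at an unadjusted p under 0.05 in limma), 2 without B10.D2 donor replicate 3 or DBA donor replicate 1, and 4 without DBA donor replicate 2. It was also 0 with no filter on dim probes, with the ordinary per-probe statistic and with the stricter filter, which left Ccl8, Ccl12, Mcpt4 and Zan untested.

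**Figure D1:**
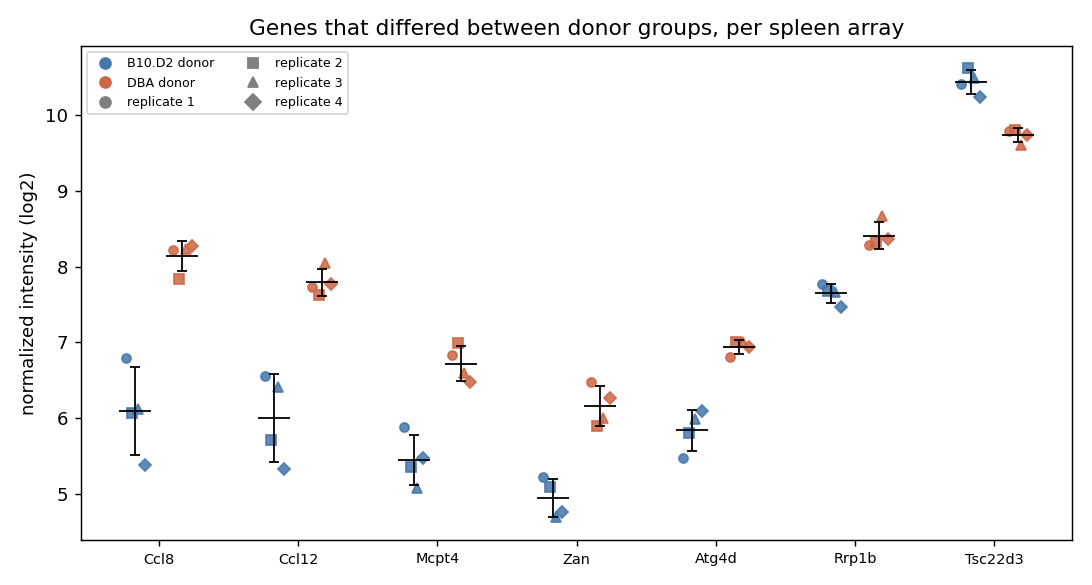
Normalized log2 intensity of the 7 named genes that passed the test, per spleen array, by donor group; points are arrays, horizontal bars are group means and whiskers are the SD over 4 arrays. Groups do not overlap for any of the 7, and Ccl8 shows the widest gap, 8.14 against 6.09.

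Genes of mast cells and basophils were higher as a group in DBA donor spleens: all 9 tested members had positive differences, with a mean of 0.45 on the log2 scale. Of the 9, 1 passed over all probes (Mcpt4) and 6 passed adjusted over the list alone. The others of these 6 were Cma1 (0.49), Cpa3 (0.60), Prss34 (0.52), Mcpt8 (0.41) and Il4 (0.46, or 0.29 without B10.D2 donor replicate 4); the first 4 are proteases of mast cells or basophils and were named after their values were seen. Hdc (0.01) and Gata2 (0.01), which both lineages also express, differed by less than their SE of 0.15 and 0.10. The list was called by camera (adjusted p = 2.8e-06) and by fry (adjusted p = 0.0183), its array means did not overlap between groups (exact permutation p = 0.0286, or 0.371 adjusted over the lists), and its adjusted p was 0.135 with an estimated correlation.

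Genes of protein folding in the endoplasmic reticulum (ER) were higher as a group, with positive differences in 19 of 20 tested members and a mean of 0.31 (camera adjusted p = 1.7e-06; adjusted p = 0.923 with an estimated correlation). Of the 20, limma called 0 over all probes (5 at an unadjusted p under 0.05) and 1 adjusted over the list alone, the chaperone Calr (log2 difference 0.72, SE 0.13, limma adjusted p = 0.0899). Hsp90b1, another ER chaperone, differed by 0.55 (SE 0.19). Plasma cell genes had a mean of 0.37 (camera adjusted p = 0.0101; adjusted p = 0.973 with an estimated correlation), with 0 of 12 members past the limma test and 3 at an unadjusted p under 0.05. Among them Creld2 differed by 0.82 and Xbp1, a transcription factor of secretory cells, by 0.52. With 1 array left out Creld2 fell to as low as 0.51, Xbp1 to 0.30 and Hsp90b1 to 0.34. Without B10.D2 donor replicate 4, whose plasma cell mean of 8.12 lay below the 8.85 to 9.44 of the other arrays of its group, the plasma cell mean was 0.13 (camera adjusted p = 0.238) and the ER mean 0.20 (camera adjusted p = 0.000456); without B10.D2 donor replicate 1 the plasma cell mean was 0.57.

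Genes of naive lymphocytes were lower as a group in DBA donor spleens, with negative differences in 10 of 11 tested members and a mean of -0.24 (camera adjusted p = 0.00253; adjusted p = 0.923 with an estimated correlation). Il7r, a receptor for a survival cytokine of lymphocytes, differed by -0.46 and Klf2, a regulator of lymphocyte trafficking, by -0.51. Of the 11, limma called 0 over all probes (5 at an unadjusted p under 0.05) and 3 adjusted over the list alone. Proliferation genes had positive differences in 25 of 27 tested members and a mean of 0.17 (camera adjusted p = 0.00253; adjusted p = 0.973 with an estimated correlation), and limma called 0 of them (2 at an unadjusted p under 0.05), with mitotic kinase Aurka at 0.45 and Plk1 at 0.35. The proliferation mean followed single arrays: 0.10 without B10.D2 donor replicate 2 (camera adjusted p = 0.0741), 0.06 without DBA donor replicate 2 (camera adjusted p = 0.274), 0.31 without B10.D2 donor replicate 4 and 0.26 without DBA donor replicate 1. B10.D2 donor replicate 4 and DBA donor replicate 2 had the highest means of both the proliferation list (9.62 and 9.72) and the erythroid list (10.35 and 10.30). With an estimated correlation 0 of the 25 lists were called, and with fry 1 (mast cell and basophil). All these list calls come with the limit that 27 of the 35 ways to split the 8 arrays into 4 and 4 called at least 5 lists.

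**Figure D2:**
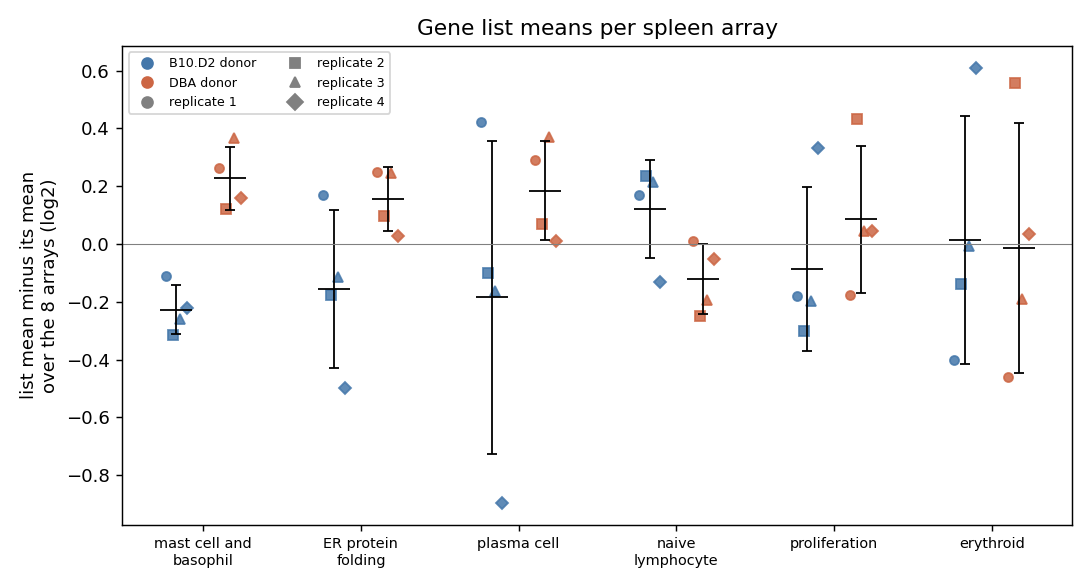
Mean normalized intensity of 6 gene lists on each spleen array, as the log2 difference from the mean over the 8 arrays; points are arrays, horizontal bars are group means and whiskers are the SD over 4 arrays. Mast cell and basophil means do not overlap between groups, whereas plasma cell, proliferation and erythroid means spread widely, with B10.D2 donor replicate 4 at -0.90 on the plasma cell list and 0.61 on the erythroid list.

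Among cytokines and chemokines, 2 of 29 tested genes passed (Ccl8 and Ccl12), both higher, and 5 higher and 1 lower passed adjusted over the list alone. The list had a mean of 0.16 and a median of 0.03 (camera adjusted p = 0.0951, called in 2 alternatives). As with the mast cell list, its array means did not overlap between groups (exact permutation p = 0.0286, or 0.371 adjusted over the lists). Il10 differed by 0.40 (SE 0.12, limma adjusted p = 0.208), and it was among those that passed adjusted over the list alone. Ifng differed by -0.11 (95% confidence interval -0.38 to 0.16; -0.19 to -0.03 with 1 array left out) and by 0.05 on its other probe. Tnf differed by -0.19 (95% confidence interval -0.44 to 0.05; -0.24 to -0.09 with 1 array left out). Il21, a cytokine of follicular helper T cells, was above background on 2 of 4 B10.D2 donor arrays and 0 of 4 DBA donor arrays, at least 1.22-fold higher in B10.D2 donor spleens, with measured means of 5.19 and 4.41 (adjusted p = 0.304 in limma with no filter on dim probes). Il2 had 0 listed probes.

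The cytotoxic effector list did not move one way. Of 18 tested genes limma called 0 over all probes (2 higher and 4 lower at an unadjusted p under 0.05), and 2 higher and 2 lower passed adjusted over the list alone. Ccl3, a chemokine made by activated T and NK cells, differed by 0.59 (SE 0.13, limma adjusted p = 0.127), while the CD8 chain gene Cd8b1 differed by -0.38 and by -0.39 on its other probe. The perforin gene Prf1 differed by -0.06 (95% confidence interval -0.37 to 0.25; -0.20 to 0.04 with 1 array left out) and Fasl by -0.26 (95% confidence interval -0.53 to 0.01; -0.32 to -0.16 with 1 array left out). Gzmb, Cd8a and Ncr1, with 1 listed probe each, were not above background on any array. Cd8b1 stood at 9.54 in DBA donor spleens and 9.93 in B10.D2 donor spleens, so the Cd8a probe does not show that CD8 RNA was absent. Type I interferon-stimulated genes had a mean of -0.05 (camera adjusted p = 0.787; -0.11 to 0.03 with 1 array left out), with Isg20 at 0.42 and Oasl2 at 0.27 (0.06 on its other probe). Interferon-gamma-induced genes had a mean of 0.03 (camera adjusted p = 0.920; -0.02 to 0.07 with 1 array left out), with Ido1 at 1.06 (SE 0.41, limma adjusted p = 0.278; 0.59 without B10.D2 donor replicate 4) and Socs1 at -0.31. In the list of inhibitory receptors and exhaustion, Rgs16 differed by 0.62 (0.41 to 0.74 with 1 array left out; mean of the list 0.12, camera adjusted p = 0.216, 0.03 to 0.17 with 1 array left out).

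The other B and T cell lists were not called by camera with the preset correlation, and their means followed single arrays. Mature B cell genes had a mean of -0.11 (camera adjusted p = 0.0828; called in 8 of 25 alternatives, camera on ranks and both changes of filter among them, and -0.19 to -0.04 with 1 array left out), with Cd79a at -0.37, Ebf1 at 0.42 and Ms4a1 at -0.19 (-0.28 to -0.09 with 1 array left out). Germinal centre B cell genes had a mean of 0.08 (camera adjusted p = 0.785), with Bcl6 at 0.06 (95% confidence interval -0.27 to 0.39). T follicular helper genes had a mean of 0.10 (camera adjusted p = 0.383), with Il4, also a member of the mast cell and basophil list, at 0.46 and Btla at -0.42. Without B10.D2 donor replicate 4 these turned to -0.10 for the germinal centre B cell list, -0.07 for Bcl6 and -0.03 for the T follicular helper list, so their direction is open. Pan T cell genes had a mean of -0.10 (camera adjusted p = 0.286; called in 2 alternatives, and -0.19 to -0.02 with 1 array left out), with Thy1 at -0.28. Cd4 differed by -0.25 (95% confidence interval -0.67 to 0.16; -0.42 to -0.13 with 1 array left out). Regulatory T cell genes had a mean of 0.03 (camera adjusted p = 0.785; -0.10 to 0.10 with 1 array left out), with Socs2 at 0.65 and Tnfrsf4 at -0.43. The plasma cell surface marker Sdc1 differed by 0.17, or 0.38 on its other tested probe (0.04 to 0.30 with 1 array left out on the first). The intervals of Bcl6 and Cd4 lie within a log2 difference of 1 in either direction.

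Several macrophage and stromal genes had lower values in DBA donor spleens, with no gene past the limma test over all probes. Siglec1, a sialic acid receptor of marginal metallophilic macrophages, differed by -0.52 (SE 0.11, limma adjusted p = 0.127) and the scavenger receptor Marco by -0.40. Gpnmb, of the red pulp and tissue macrophage list, went the other way, at 0.59 (SE 0.29, limma adjusted p = 0.386). It is also in the list of genes that vary between DBA/2 and C57BL strains. Of 26 tested members of the macrophage list, 9 had positive and 17 negative differences. The red pulp and tissue macrophage list had a mean of -0.06 (camera adjusted p = 0.286; -0.11 to -0.02 with 1 array left out). In the stroma and endothelium list (mean -0.11, camera adjusted p = 0.0828; called in 7 alternatives, and -0.16 to -0.07 with 1 array left out) the endothelial cadherin Cdh5 differed by -0.51 and the chemokine Cxcl12 by -0.35. Of the list, 2 of 29 members, both lower, passed adjusted over the list alone. Dendritic cell genes had a mean of -0.15 (camera adjusted p = 0.0828; called in 2 alternatives), with Siglech, a marker of plasmacytoid dendritic cells, at -0.62 and at -0.25 on its other probe. The megakaryocyte and platelet list had a mean of 0.11 (camera adjusted p = 0.0828; called in 4 alternatives, and 0.02 to 0.20 with 1 array left out). The neutrophil and granule list had a mean of -0.05 (camera adjusted p = 0.785; -0.15 to 0.10 with 1 array left out), with Mmp9 at -0.50. The list of immediate early and heat shock genes, a sign of RNA handling, had a mean of -0.03 (camera adjusted p = 0.920; -0.06 to 0.01 with 1 array left out). The NK cell list had a mean of 0.00132 but a median of -0.08, the monocyte list a mean of 0.00943 and a median of -0.04, and the erythroid list a mean of -0.03 with an upward camera statistic (adjusted p = 0.918, 0.785 and 0.925). All 3 means changed sign with 1 array left out. The list of genes that vary between DBA/2 and C57BL strains had a mean of 0.10 (camera adjusted p = 0.216; 0.06 to 0.12 with 1 array left out), with Ide at 0.68. The list of pancreas and fat had 2 tested members, too few for camera, Cela1 at -0.28 (0.30 without B10.D2 donor replicate 4) and Lep at 0.05 (-0.07 to 0.11 with 1 array left out).

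**Figure D3:**
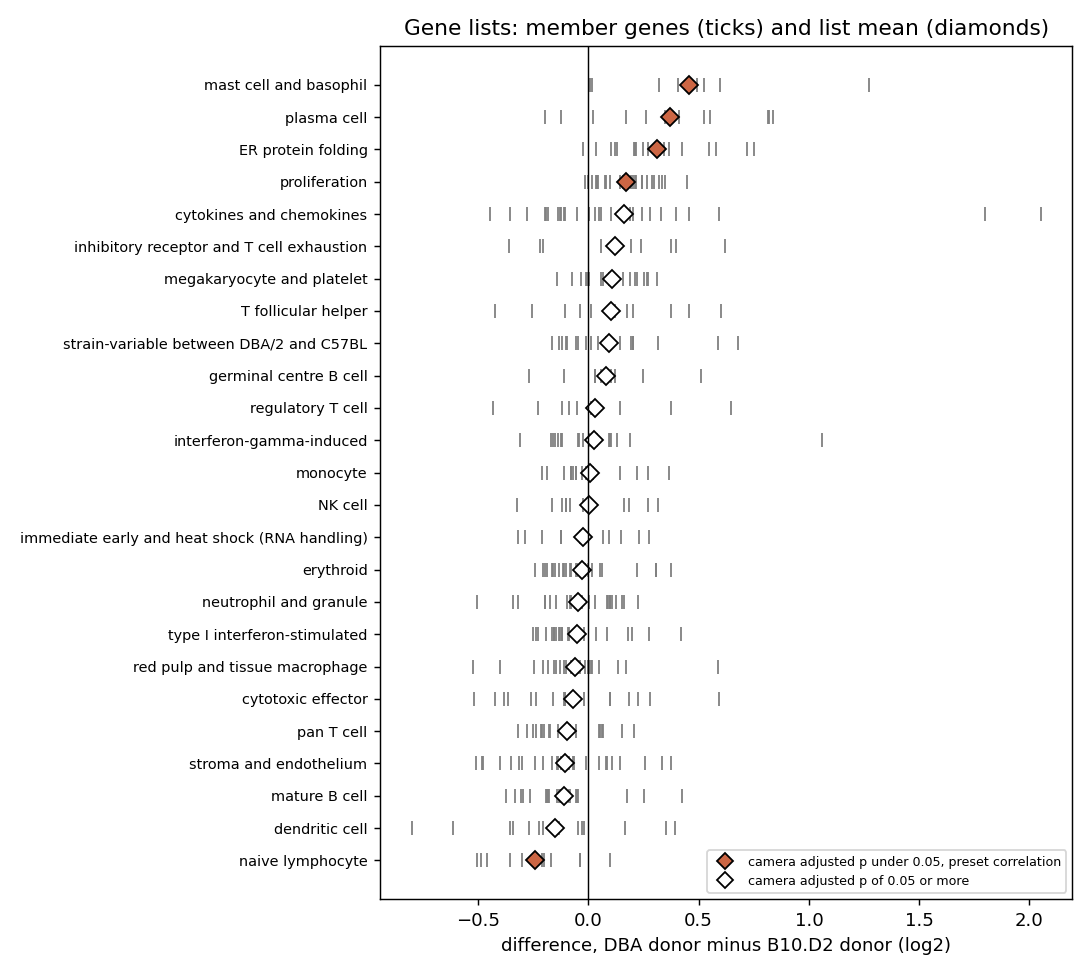
Differences between donor groups (DBA donor minus B10.D2 donor, log2) of the members of the 25 tested gene lists; grey ticks are genes, diamonds are list means, and filled diamonds mark lists that passed camera with a preset correlation. The mast cell and basophil list lies highest, with a mean of 0.45, and the naive lymphocyte list lowest, with a mean of -0.24.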

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

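The count of splits for all probes called and the tests of array brightness and of stromal genes were chosen after the result they measure was seen; the other tests in this part were chosen before. In 11 of 182 groups of 4 arrays, 1 array stood far from the others of its group, where chance gives about 9.1. The gap to the nearest other array is given as a share of the group's whole range. B10.D2 donor replicate 4 accounted for 7 of the 11. It was highest for the mean of type I interferon-stimulated genes (8.34 against 8.03, share 0.98), for the mean of the pancreas and fat list (7.92 against 6.67 to 6.84, share 0.866) and for Cela1, a pancreatic elastase (10.85 against 8.30 to 8.65, share 0.864). It was lowest for the means of mature B cell genes (9.64 against 9.93 to 9.98, share 0.842), germinal centre B cell genes (7.81 against 8.50 to 8.61, share 0.863) and pan T cell genes (7.86 against 8.24 to 8.26, share 0.95), and for Mef2b (6.38 against 8.19 to 8.51, share 0.848). These 7 overlap, since Cela1 is a member of the pancreas and fat list and Mef2b of the germinal centre B cell list. Among called genes, Ccl8 was lowest on DBA donor replicate 2 (7.84 against 8.22 to 8.27, share 0.884). Creld2 was lowest on DBA donor replicate 4 (10.38 against 10.77 to 10.85, share 0.832). On B10.D2 donor replicate 1, Slc4a1 (13.76 against 14.11 to 14.15, share 0.882) and Cxcl12 (11.78 against 11.93 to 11.96, share 0.85) were lowest.

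Of the 35 splits of the 8 arrays into 4 and 4, 2 called at least the 9 probes that the donor labels called: the labels themselves and 1 other, with 29. The remaining 33 called 0 probes. For probes at least 2-fold apart it was likewise these 2 splits, with 7 for the labels and 12 for the other, and 0 for the remaining 33. For gene lists it was 27 splits, with 5 for the labels and 18 for the highest other. Chance can therefore not be excluded for any of the 3 counts at a share of 0.05, and 2 of 35 is the least that a single other split allows.

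The split with 29 called probes exchanges B10.D2 donor replicate 4 and DBA donor replicate 1. Exchanged samples remain open: on the 50 probes that best separate the other 6 arrays, 1 of the 2 arrays lay on the side of its label, with B10.D2 donor replicate 4 at 0.777 and DBA donor replicate 1 at 0.53 on a scale from 0 (B10.D2 donor mean) to 1 (DBA donor mean). When each of the 8 arrays was held out in turn, 8 of 8 lay on the side of their label. In that check the other of the 2 arrays helped to choose the probes under its own label, so it cannot exclude an exchange. Unequal erythroid RNA is a candidate explanation. Within the groups of that split, its called probes outside the erythroid list had a median correlation of 0.637 with the erythroid list mean. The 95th percentile in random sets of probes was 0.36. The called probes were picked together and may move together, which random sets do not, so this does not single out erythroid RNA. Whether the erythroid difference came from the animals or from sampling of the tissue was not tested.

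Ccl8, Ccl12 and 5 mast cell or basophil genes (Mcpt4, Cma1, Cpa3, Prss34 and Mcpt8) were higher in DBA donor spleens by a median of 0.60. Before normalization between arrays, the mean of these 7 genes was higher on the dimmer DBA donor arrays, by 0.668. Its 95% confidence interval was 0.47 to 0.86, and the median difference was 0.23 for the 7 genes and -0.37 for all tested probes. The genes had been picked for being higher after normalization, which nearly sets this outcome. The test therefore cannot exclude a part for array brightness. This was the third form of the test; the first, against brightness, and the second, for it with a ratio of 0.39, were dropped because normalization and the shift of all probes fixed their outcomes. Unequal erythroid RNA does not account for the set, since erythroid means differed by only -0.03 between groups. With that mean as a covariate the called probes rose from 9 to 71, and the median difference of the set was 0.994 of its size without it. Group means this close leave the covariate little room to change the difference, so the ratio adds no support. More capsule or fat in the DBA donor samples stays open. The stroma and endothelium list (mean -0.106) was bright, held no fat genes and had members that went both ways. Chance stays open too, as does a strain variant under the probes of Ccl8 and Mcpt4, which had 1 tested probe each. A difference in mast cells, basophils or chemokine-producing cells that follows the donor strain is 1 further hypothesis that may account for the set.

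Atg4d, Zan and Rrp1b were higher in DBA donor spleens, and Atg4d and Zan had 1 tested probe each. A variant between the donor strains under a single probe could give such a difference without one in RNA level. Ccl8 and Mcpt4 also had 1 tested probe each, so this doubt covers them too. Of 42 genes with a probe at an unadjusted p under 0.001 and another tested probe, 61.9% had another probe that differed the same way at an unadjusted p under 0.05, which lies between the limits set for and against this explanation. With no probe sequences used here, a probe effect and a difference in RNA cannot be told apart for Atg4d, Zan, Rrp1b, Ccl8 or Mcpt4. A difference by donor strain also stays open.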

How the results depend on the processing

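The settings that left out both arrays with the highest erythroid mean or took the erythroid mean as a covariate were chosen after seeing the data. Against 9 called probes, limma called 18 after 75th percentile scaling, 45 with array quality weights, 71 with the erythroid covariate, 35 at an adjusted p under 0.10, 2 at one under 0.01, and 0 with no filter, the stricter filter or the ordinary per-probe statistic (2758, 1589 and 1789 probes at an unadjusted p under 0.05). Leaving out 1 array gave 0 to 11. No filter adds probes to adjust for and a lost array removes samples. The stricter filter, a detection p under 0.01 on all 8 arrays, left Ccl8, Ccl12, Mcpt4 and Zan untested. Its 0 calls therefore say nothing about these genes, and other causes were not tested. Against 7 probes at least 2-fold apart there were 1 without background correction, 2 with normexp at offset 50, 4 with neqc at offset 50, 11 with the erythroid covariate, 0 with no filter, the stricter filter or the ordinary statistic, and 0 to 8 with 1 array left out; a larger offset shrinks differences by construction. Against 5 lists, 8 were called with no filter, 0 by camera with an estimated correlation, 1 by fry and 5 to 9 with 1 array left out. Without both high-erythroid arrays 8 probes (7 of them among the 9), 7 at least 2-fold apart and 7 lists were called. The erythroid list mean reversed without B10.D2 donor replicate 4, to 0.17 (adjusted p = 0.0376), and ran from -0.22 to 0.17 over lost arrays. A tally of 1456 values held the gene values and the number of lists called under each alternative. In it 1382 stayed the same, 69 became weaker, 5 stronger and 0 reversed. For a gene, this means a call that was kept, lost, gained or reversed, and for the number of lists it means a change in size. Of the genes only Calr gained the call, in 2 alternatives. For the 625 list values, judged by their calls as the genes were, these counts were 584, 14, 26 and 1. Among the 1382 and 584 together, 45 values that were uncalled in both settings changed sign. Ccl8 ran from 1.19 to 2.29, Ccl12 from 0.97 to 1.98, Mcpt4 from 0.53 to 1.42, Zan from 0.42 to 1.35, Atg4d from 0.51 to 1.19, Rrp1b from 0.56 to 0.81, Tsc22d3 from -0.80 to -0.56 and the mast cell and basophil mean from 0.21 to 0.50; without background correction Zan lost its call (0.42). Whether replicate numbers pair the arrays is open. Deviations of same-numbered arrays correlated at 0.34, -0.35, 0.05 and 0.04. Arrays with unlike numbers were not set beside them, so these values cannot exclude pairing. The replicate block, in which Tsc22d3 and Rrp1b lost their calls, gave 7 called probes, 7 at least 2-fold apart and 5 lists. A slide block was not run, since the files name no slide. Signal over background limits Gzmb, Cd8a, Ncr1 and Il21.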

Other observations

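The lists in this part were written after the best-ranked genes had been seen, without the members that prompted them. Ribosome biogenesis genes were higher as a group in DBA donor spleens, with positive differences in 20 of 21 tested members and a mean of 0.19 on the log2 scale. Array means ran from 9.53 to 9.68 in DBA donor spleens and from 9.35 to 9.48 in B10.D2 donor spleens (exact permutation p = 0.0286, or 0.114 adjusted over the 4 lists; camera p = 2.4e-08). With an estimated correlation p was 0.0474, or 0.190 adjusted over the 4 lists of this part, so that call was lost. Limma called 0 of the 21 (9 at an unadjusted p under 0.05), with Rrp9 at 0.44, Nop56 at 0.33 and the nucleolar protein Npm1 at 0.24. Higher ribosome production in DBA donor spleens is a hypothesis that may account for this mean of 0.19, found and tested on the same data.

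Tsc22d3 is induced by glucocorticoids and by FoxO transcription factors. Other genes induced by these had a mean of -0.17, with negative differences in 10 of 15 tested members (camera p = 0.00428, exact permutation p = 0.143; p = 0.262 with an estimated correlation). Sgk1 differed by -0.47, Ddit4 by -0.51, Txnip by -0.33 and Sesn1 by -0.38, and limma called 0 of the 15 (0 higher and 7 lower at an unadjusted p under 0.05). The tests split, so a lower level of this group was not established.

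Sterol synthesis genes had a mean of 0.0813 (camera p = 0.0117, exact permutation p = 0.229; p = 0.209 with an estimated correlation, so that call was lost), with Msmo1 at 0.32 and Fdps at 0.24. Genes of alternatively activated macrophages had a mean of 0.0364 and a median of -0.03 (camera p = 0.973, exact permutation p = 0.743), although Retnla differed by 1.01 (SE 0.35, limma adjusted p = 0.243). Il21 was detected on 2 B10.D2 donor arrays and no DBA donor array. Probes detected on at least 2 B10.D2 donor arrays and no DBA donor array numbered 125, against 231 for the reverse. With at least 3 arrays in place of 2 these counts were 36 and 74, a ratio of 0.486. Brighter B10.D2 donor arrays thus did not bring more probes of either kind.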
